A study of Mus musculus with 6 samples.

How the data were processed

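Tibialis anterior muscles of 3-month-old male mice, 3 wild type and 3 labelled as PGC-1β transgenic, were profiled on 1-colour Illumina Mouse WG-6 v2 arrays, 1 array per sample. Groups were taken from the genotype labels. The labels do not say that each array is a separate animal, so p-values measure the spread between these arrays, which may be technical. Per the labels' protocols, total RNA was amplified with a T7 oligo-dT primer and labelled as biotinylated cRNA, and the submitters' processing notes name GenomeStudio, with no version.

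Per the file headers, the deposited unnormalized table gives an intensity and a detection p-value per probe and array. Its intensity values were neither background-subtracted nor scaled between arrays, with array medians of 73.3 to 78.8 and maxima of 27247.7 to 34205.1. The detection p-value that the authors deposited beside each intensity compares a probe with the negative controls of its array, and in every column it never rose with the signal (0 order breaks). The second table that the authors deposited holds intensity values on a linear scale with array medians of 6.2 or 6.3, a common maximum of 30836.5 and a common minimum of -22.6, which shows background subtraction and quantile normalization. Each of its columns ranked the probes as the matching unnormalized column did (Spearman correlation across probes of at least 0.999995). Which background setting the authors used is not given in the sources used here.

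The unnormalized intensities were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with negative-control parameters inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2 (neqc). Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, 17166 of 45281. Gene names came from the platform annotation. It gives 1 symbol for 34885 probes, several for 18 and none for 10378, and 34807 probes were matched by Entrez ID to the RefSeq table used here, which changed 0 symbols. No coordinates were used. Of the probes kept, 14803 had 1 symbol, and the probe with the highest mean log2 signal stood for its gene, which gave 9978 genes. Of 3461 genes with 2 or more probes kept, 67 had probes called in opposite directions, among them 2 named here, Mbp and Rab3a. A sample with more probes above background has more genes measured directly, and differences for probes near background are compressed by the offset.

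Genotypes were compared with lmFit and eBayes on log2 values, two-sided, with Benjamini-Hochberg adjustment over the 9978 genes and a threshold of 0.05. Every adjusted p of a gene is from limma. A gene with no probe above background on any array of a group has only a bound there. It is given as "at least N-fold", the brighter group's mean against the dim group's mean of the higher of the lowest detected signal and the probe's own. Ppargc1b was also tested with an exact two-sided permutation test.

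There were 38 gene lists covering mitochondria, fibre types, metabolism, vessels, immune and other cell types. They were fixed before the data were examined, and 714 of their 887 entries were measured. Lists with at least 5 measured members were tested with camera in limma at its preset correlation of 0.01, adjusted over the lists. An estimated correlation per list and fry were alternatives. Counts of members use the adjustment over all genes, and the count adjusted over the list alone is given where it differs. The named genes were fixed by rule before the data were examined: Ppargc1b; the 10 largest rises and 10 largest falls among called genes with non-overlapping groups, leaving out clone-type names; up to 4 called members per list by size of change, or up to 2 with the smallest p where none was called; and a fixed set of regulators, myosins and vessel factors. Other genes named in the closing section, and a list of targets of the repressor Rest, were chosen after their values or those of related genes were seen.

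The testing step was tried on simulated log2 values for the comparison of transgenic against wild type, over 9978 genes with the real means and variances and 200 genes changed singly. It called 29 of 67 genes changed 1.5-fold, 47 of 67 changed 2-fold and 65 of 66 changed 4-fold, and 6 of 9756 unchanged genes. A simulated shift of 1 list of 22 genes was called, with 1 other list. Genes were simulated as independent, so this does not test how lists of correlated genes are called. The simulation began after normalization, so background correction, normalization and the detection filter were not tested. Far fewer genes were changed than the 5613 of 9978 called in the data, so the shares called do not carry over to the data.

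Alternatives changed the background correction, normalization, dim-probe filter, probe summary, variance model, array weights, replicate block, set test and the arrays included. The authors' value table was tried as well. The BeadChip as a block was not run, because the columns used here do not name it. After the data were examined, a scaling to the median of probes detected on all arrays and a count restricted to genes measured in both groups were added.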

Results

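Gene expression was measured in the tibialis anterior, a mostly fast-twitch muscle of the lower hindlimb, of 3-month-old male mice of 2 genotypes. There were 3 wild-type arrays and 3 arrays labelled as carrying a transgene for PGC-1β, the transcriptional coactivator encoded by Ppargc1b, which is known to raise genes of mitochondrial respiration. Each array was a 1-colour Illumina Mouse WG-6 v2 BeadChip array with 45281 probes. The number of probes with a detection p-value under 0.05 was 15338, 15691 and 15614 on the wild-type arrays and 17588, 17604 and 17525 on the arrays labelled transgenic. The number of arrays, 3 per group, limits the precision of every value below. Levels are log2 signals after background correction and quantile normalization, and changes are transgenic minus wild type. As in every comparison here, "rose" and "fell" refer to adjusted p-values under 0.05 in limma.

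Ppargc1b, the gene named by the genotype, was read first because it checks the labels. Its signal was lower, not higher, in the arrays labelled transgenic. The array carries 1 probe annotated to Ppargc1b (ILMN_2771709), and its log2 signal was 9.23 ± 0.33 (SD, n = 3) in wild type and 7.91 ± 0.32 (SD, n = 3) in the arrays labelled transgenic. The unnormalized signals were 497.2, 648.7 and 708.9 on the wild-type arrays and 281.3, 373.4 and 309.8 on the others. The log2 change was -1.32 (SE 0.21, adjusted p = 0.000734), and all 3 values lay below the 3 wild-type values. An exact two-sided permutation test on the 6 values gave p = 0.1, the smallest that 3 arrays against 3 allow. Which part of the mRNA this probe matches, and whether the transgene holds that part, is not known here. The direction of every difference below therefore rests on the genotype labels alone, and the groups are called wild type and labelled transgenic. The related coactivator Ppargc1a also fell, by 1.61 on the log2 scale (adjusted p = 0.000314), and was above background on 2 of the arrays labelled transgenic.

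The next question was how far the 2 genotypes differed over all genes. The difference was broad: of 9978 genes tested, 5613 (56.3%) passed the threshold, 2801 higher and 2812 lower in the arrays labelled transgenic. Of these, 1082 rose and 644 fell by at least 2-fold, and 283 rose and 94 fell by at least 4-fold. Sln, encoding sarcolipin, a small inhibitor of the sarcoplasmic reticulum calcium pump, had the largest rise among genes above background on at least 1 array of each group, from 7.40 ± 0.10 to 14.02 ± 0.16 (SD, n = 3), a 98.5-fold difference. Myl3, encoding the slow-muscle and ventricular essential myosin light chain, had the largest fall among such genes, from 12.34 ± 0.28 to 5.73 ± 0.23 (SD, n = 3), a 97.5-fold difference. The within-group correlations between arrays were 0.987 to 0.992 across genes, against 0.901 to 0.921 between groups, and the leading principal component held 86.3% of the variance. In 6367 genes (63.8%) the 3 values of one group all lay beyond those of the other, where chance alone gives 10%. Among the genes that rose, 479 had no probe above background on any wild-type array, and 37 of those that fell had none on any array labelled transgenic, so for such genes a fold is given as a lower bound. With each array scaled to its median in place of quantile normalization, the median change of all genes moved from -0.03 to 0.19, and 3772 genes were higher and 1607 lower.

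**Figure D1:**
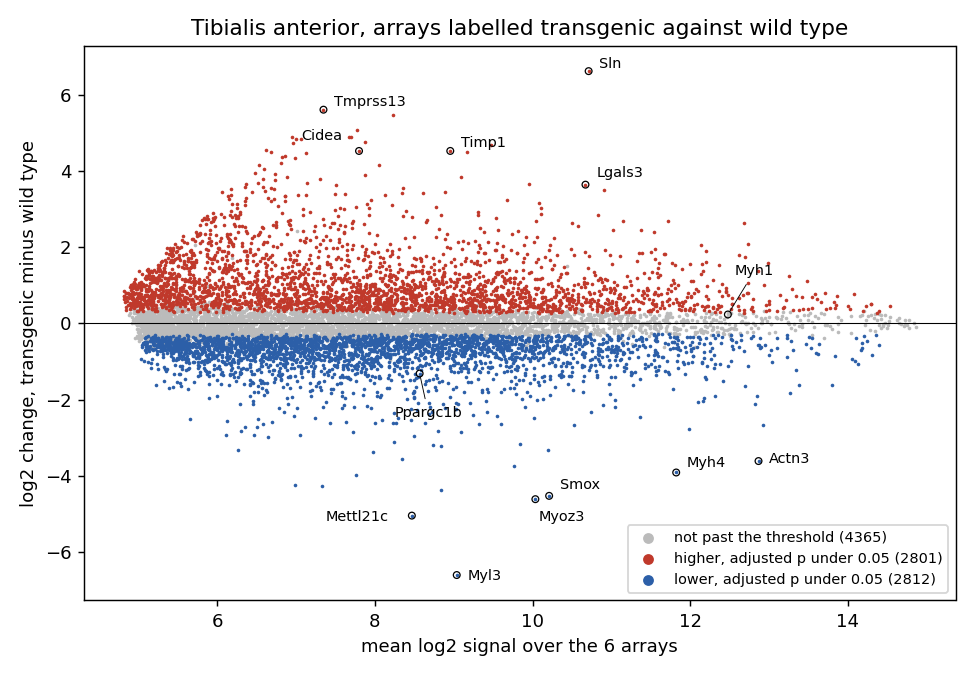
Log2 change (transgenic minus wild type, vertical axis) against mean log2 signal over the 6 arrays (horizontal axis) for the 9978 genes tested, each point a gene. Red points are the 2801 genes that rose and blue points the 2812 that fell; Sln and Myl3 lie at the extremes of the fitted changes, and Ppargc1b lies among the genes that fell.

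Besides Sln, the 10 genes with the largest fitted rises among those whose groups did not overlap mixed immune genes with genes usually expressed outside muscle. Fitted rises of genes near background are compressed and do not rank these genes against others at background in wild type: that of Cplx1 ranged from 3.42 to 9.37 over the alternatives, and that of Sln from 6.23 to 6.76. Dhx58, which encodes the RNA helicase LGP2, rose by 5.08, the chemokine gene Ccl8 by 4.90, the Fc receptor gene Fcgr4 by 4.89 and Plac8 by 4.76 on the log2 scale. On the wild-type arrays Dhx58 and Ccl8 were above background on 1 each, and Fcgr4 and Plac8 on 2 each. Rnf208, encoding a RING-finger protein, rose by 5.46. The other 4 had no probe above background on any wild-type array: the serine protease gene Tmprss13 was at least 30.2-fold higher, Lce1f at least 18.8-fold, the nucleoside transporter gene Slc29a4 at least 18.1-fold and Cplx1, encoding the synaptic protein complexin 1, at least 17.9-fold. After Myl3, the largest fitted falls were those of the methyltransferase gene Mettl21c (-5.05), the fast-fibre Z-disc gene Myoz3 (-4.62), the spermine oxidase gene Smox (-4.53), the protein phosphatase inhibitor gene Ppp1r1a (-4.38), Gdap1 (-4.26), Cyp4f39 (-4.25), Fam131a (-3.98), the fast myosin heavy chain gene Myh4 (-3.91) and the alanine aminotransferase gene Gpt2 (-3.74). On the arrays labelled transgenic Gdap1 was above background on 2 and Cyp4f39 on 1. The adjusted p of these 20 genes ranged from 2.28e-08 for Sln to 3.98e-05 for Myh4.

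Fast-fibre genes, among them the IIB myosin heavy chain of glycolytic fibres, were lower, and slow-fibre genes went both ways. Of 16 fast-fibre genes measured, 9 fell and 0 rose, and the list was lower than other genes (camera adjusted p = 0.0024, and adjusted p = 0.256 with an estimated correlation). The macrophage and matrix lists rose in the same arrays, with medians of 2.24 and 1.43. Myh4, the IIB myosin heavy chain, fell from 13.78 ± 0.15 to 9.87 ± 0.87 (SD, n = 3), and Actn3, encoding the fast-fibre α-actinin, fell by 3.61 on the log2 scale. Mylk2, the skeletal myosin light chain kinase, fell by 2.77. The change of Myh1, the IIX myosin heavy chain, was 0.23 (adjusted p = 0.226). It was 0.41 and past the threshold without transgenic replicate 1 (adjusted p = 0.0226), and turned to -0.0072 with each array scaled to the median of the probes detected on all arrays. A dimmer Myh1 probe had a change of 0.35. Its unnormalized signals were 293.1, 298.9 and 225.5 in wild type and 332.2, 444 and 411.7 on the others, without overlap. The slow-fibre list did not pass (adjusted p = 0.16): 7 of its 13 genes rose and 3 fell, or 8 and 3 adjusted over the list alone. Tnnc1, the slow and cardiac troponin C, rose by 2.70, the muscle LIM protein gene Csrp3 by 2.68 and the calsequestrin gene Casq2 by 2.21, while Myl3 fell as above. The IIA myosin gene Myh2 had 0 annotated probes and the slow myosin gene Myh7 had 3, none of them above background on any array.

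Genes of calcium handling and of sugar use fell, in the same arrays in which the macrophage and matrix lists rose, with medians of 2.24 and 1.43. Among 17 calcium-handling genes 13 fell and 2 rose, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.000147, and adjusted p = 0.256 with an estimated correlation). The junctophilin genes Jph2 and Jph1, whose products tether the calcium stores to the surface membrane, fell by 2.65 and 2.14, and the kinase gene Camk2a fell by 2.85. Sln was one of the 2 that rose. Of 17 glycolysis genes 14 fell and 2 rose (camera adjusted p = 0.000891, and adjusted p = 0.256 with an estimated correlation). Fbp2, the muscle fructose bisphosphatase, fell by 3.21, the glycerol phosphate dehydrogenase gene Gpd1 by 2.62 and the lactate exporter gene Slc16a3 by 2.51. The Slc16a3 change was -1.03 and not past the threshold in the authors' value table (adjusted p = 0.192). It was -0.70 without wild-type replicate 1, but the filter and the choice of probe were applied anew there. Another probe can then stand for the gene, so this value does not show that the fall rests on that array. Hk1, the hexokinase form common outside skeletal muscle, rose by 2.56, above background on 1 wild-type array, and Slc16a3 was on 1 array labelled transgenic. Of 15 genes of glycogen and glucose uptake 12 fell and 1 rose (camera adjusted p = 0.000374, and adjusted p = 0.256 with an estimated correlation). Pygm, the muscle glycogen phosphorylase, fell by 2.46, and the phosphorylase kinase subunit genes Phka1, Phkb and Phkg1 fell by 2.82, 2.41 and 2.32.

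Mitochondrial genes rose in part, and the ribosome of the organelle gave the mitochondrial list with the lowest p. The macrophage and matrix lists rose in the same arrays, with medians of 2.24 and 1.43. The balance depended on the scaling: of 191 genes in 7 mitochondrial lists 93 rose and 11 fell, but 57 rose and 33 fell with arrays scaled to detected probes. Of 70 mitochondrial ribosome genes 43 rose and 3 fell (camera adjusted p = 9.83e-07, and adjusted p = 0.256 with an estimated correlation). Mrpl46 rose by 1.69, Mrps5 by 1.41 and Mrpl3 by 1.27. Of 25 genes of mitochondrial import and dynamics 13 rose and 2 fell (camera adjusted p = 0.00558, and adjusted p = 0.256 with an estimated correlation), led by the ADP/ATP carrier gene Slc25a5 (2.07) and the import chaperone gene Timm10 (1.85). Of 20 complex IV genes 9 rose and 0 fell (camera adjusted p = 0.00558, and adjusted p = 0.302 with an estimated correlation), among them Cox6a1 (1.46) and the assembly gene Sco1 (1.23). Of 17 TCA cycle genes 10 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.377 with an estimated correlation), with Dlst (0.99) and Idh3b (0.81) foremost. The lists of complex IV, the TCA cycle and mitochondrial import no longer passed when arrays were scaled to a median, with adjusted p up to 0.436, 0.431 and 0.119.

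Other lists of oxidative metabolism did not pass, although complex I passed in 7 and complexes II and III in 6 of 19 alternatives. In complex I 13 of 34 genes rose and 2 fell (camera adjusted p = 0.0542), with Ndufb7 (0.77) and Ndufs8 (0.75) up and Ndufb2 (-0.74) down, and in complexes II and III 5 of 11 rose and 0 fell (adjusted p = 0.0654), with Cyc1 (0.999) largest. Over the 19 alternatives adjusted p ranged from 0.0017 to 0.954 for complex I and from 0.0064 to 0.839 for complexes II and III. Without transgenic replicate 1 they were 0.00961 and 0.0187, and without transgenic replicate 2 they were 0.00967 and 0.0235. Genes above background only on the arrays labelled transgenic were not tested there, and the median change of all genes was -0.076 and -0.065, against -0.034. With only probes detected on all arrays the lists passed as well (camera adjusted p = 0.0144 and 0.0275). Without transgenic replicate 3 such genes were also not tested and the median change of all genes was -0.076, yet neither list passed. The change of genes tested therefore did not give a pass by itself in every case. Its part in the other passes cannot be told apart from reliance on single arrays. In complex V 2 of 15 rose and 2 fell (adjusted p = 0.614): the inhibitor gene Atpif1 rose by 1.22 and Atp5g2 fell by 0.58. In fatty acid oxidation 11 of 24 rose and 4 fell (adjusted p = 0.226). Etfdh rose by 1.06 and Acadvl by 0.85, while the uncoupling protein gene Ucp3 fell by 1.52. Relative to other genes, complex I, complex V and fatty acid oxidation turned to lower with each array scaled to a median. Among 21 regulators of mitochondrial biogenesis 6 rose and 5 fell (adjusted p = 0.591). The orphan receptor gene Esrrb rose by 2.14, the deacetylase gene Sirt3 by 1.18, Tfam, encoding the mitochondrial DNA packaging factor, by 0.94, Gabpa by 0.82 and Esrra by 0.42, the last with adjusted p = 0.0126 and no call under the scaling to detected probes. Prkaa2, a catalytic subunit gene of AMP-activated kinase, fell by 1.71. Nrf1 had a change of -0.16 (adjusted p = 0.353).

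**Figure D2:**
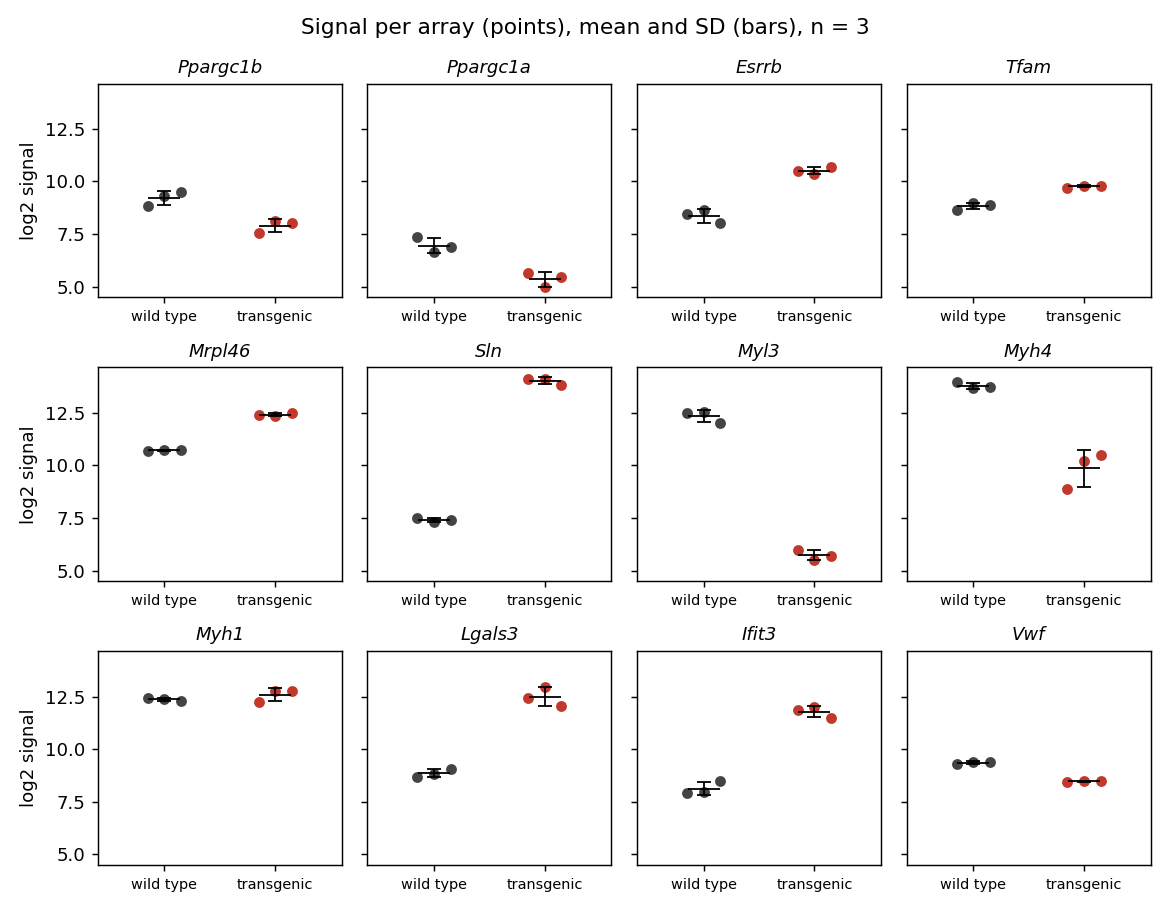
Log2 signal (vertical axis) of 12 genes on each of the 6 arrays, with the mean and SD of each group (n = 3). Ppargc1b and Ppargc1a lie lower in the arrays labelled transgenic, Myh4 falls from 13.78 to 9.87, and the values of the brighter Myh1 probe overlap between the groups.

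Genes of immune cells, interferon response and connective tissue rose together. Of 25 macrophage and immune markers 23 rose and 0 fell, with 23 and 1 adjusted over the list alone (camera adjusted p = 3.62e-11, and adjusted p = 0.256 with an estimated correlation). The median change of the list was 2.24. Lgals3, encoding galectin-3 of activated macrophages, rose from 8.85 ± 0.19 to 12.49 ± 0.45 (SD, n = 3), Cd52 by 3.44, the Fc receptor γ-chain gene Fcer1g by 3.17 and the complement gene C1qb by 2.88. All 18 interferon-response genes measured rose (camera adjusted p = 2.89e-09, and adjusted p = 0.256 with an estimated correlation), among them the antiviral genes Ifit3 (3.66) and Rsad2 (3.25), and Irf7, which was at least 8.78-fold higher. Of 22 fibroblast and matrix genes 21 rose and 0 fell (camera adjusted p = 3.62e-08, and adjusted p = 0.256 with an estimated correlation). The microfibril gene Mfap5 rose by 2.34, the fibronectin gene Fn1 by 2.17, Col6a2 by 2.11 and the biglycan gene Bgn by 1.97.

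Vessel cell markers did not move with the immune and matrix genes. Of 25 endothelial markers 7 fell and 1 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.109), with Vwf at -0.90, the water channel gene Aqp1 at -0.73 and Ly6c1 at 0.54, which was 0.34 and not past the threshold with arrays scaled to detected probes (adjusted p = 0.0564). Of 15 pericyte and smooth muscle markers 7 fell and 1 rose (adjusted p = 0.0993), led by Abcc9 (-1.54). The endothelial list passed, as lower, in 2 of 19 alternatives (no filter on dim probes, adjusted p = 0.0292, and arrays scaled to detected probes, adjusted p = 0.0422; range up to 0.33), and the pericyte list in 1 (no filter, adjusted p = 0.0322; range up to 0.205). Among 20 angiogenic factors 7 rose and 5 fell (adjusted p = 0.419): Esm1 rose by 2.19, Tgfb1 by 1.72 and Angptl4 by 1.55, while Vegfa, the main vessel growth factor, fell by 0.69 (adjusted p = 0.00744). Of 25 genes listed as antiangiogenic 16 rose and 3 fell (camera adjusted p = 0.00462, and adjusted p = 0.256 with an estimated correlation). Among the members that rose were the protease inhibitor gene Timp1 (4.53), Cxcl10 (at least 9.32-fold), Cxcl9 (3.36) and Isg15 (3.23), the last 3 of them interferon-induced genes, and the macrophage list rose in the same arrays with a median of 2.24. Thbs1, encoding thrombospondin 1, had 1 probe, which was not above background on any array.

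The lists of regeneration, denervation, myokine and heat shock genes were also higher. Of 13 satellite cell and regeneration genes 9 rose and 2 fell (camera adjusted p = 0.015, and adjusted p = 0.256 with an estimated correlation). The perinatal myosin gene Myh8 rose by 3.85, the adhesion gene Ncam1 by 2.48, the cell cycle inhibitor gene Cdkn1a by 1.69 and Ccnd1 by 1.68. Of 15 genes of denervation and the neuromuscular junction 9 rose and 1 fell (camera adjusted p = 0.00462, and adjusted p = 0.256 with an estimated correlation). Chrng, the fetal acetylcholine receptor subunit, rose by 3.54 (above background on 1 wild-type array), Chrna1 by 1.92 and Chrnb1 by 1.19. Of 11 myokine and growth factor genes 7 rose and 1 fell (camera adjusted p = 0.0171, and adjusted p = 0.256 with an estimated correlation), with Igf2 (2.46), Angptl4 (1.55) and Fstl1 (1.35) largest. Of 12 heat shock genes 6 rose and 0 fell (camera adjusted p = 0.0171, and adjusted p = 0.256 with an estimated correlation), with Hspb7 at 2.06 and Hspb1 at 1.31. The macrophage list, with its median of 2.24, rose in the same arrays as these 4 lists. The heat shock list did not pass with arrays scaled to either median (adjusted p up to 0.303), and the regeneration and myokine lists did not with the median of all probes (adjusted p = 0.0673 and 0.0508) but did with that of the detected probes.

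Clock genes fell, in the same arrays in which the macrophage and matrix lists rose, with medians of 2.24 and 1.43. Of 13 genes of the circadian clock and its outputs 10 fell and 0 rose, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.00343, and adjusted p = 0.256 with an estimated correlation). Ciart fell by 1.18, the output gene Dbp by 1.12, Bhlhe40 by 1.05 and Per2 by 0.98. The hour at which muscles were taken is not given in the sources used here.

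The remaining 12 lists did not pass. Of 17 mitochondrial stress genes 8 rose and 4 fell (adjusted p = 0.203), with the glutathione-degrading enzyme gene Chac1 at -3.33 and the serine synthesis gene Psat1 at 1.65. Of 17 antioxidant genes 9 rose and 2 fell (adjusted p = 0.124), with the peroxiredoxin gene Prdx2 at 1.58 and Nqo1 at -1.37. Among 23 genes of lipid synthesis and storage 11 rose and 8 fell, or 11 and 9 adjusted over the list alone (adjusted p = 0.614), and the lipid droplet gene Cidea rose by 4.53 (above background on 2 wild-type arrays) while Me1 fell by 1.84. Of 19 genes of branched-chain amino acid and ketone breakdown 7 rose and 5 fell (adjusted p = 0.419), with the ketone enzyme gene Bdh1 at 2.42. Of 17 atrophy genes 5 rose and 6 fell (adjusted p = 0.614), and the ubiquitin ligase genes Trim63 and Fbxo32 fell by 1.76 and 1.42. Among 7 adipocyte markers 3 rose and 1 fell, or 3 and 2 adjusted over the list alone (adjusted p = 0.419), with Cidec at 1.82 (above background on 2 wild-type arrays) and Adipoq at 1.71. Of 7 Schwann cell and nerve markers 2 rose and 3 fell (adjusted p = 0.84): Mal was at least 4.04-fold higher, and Sox10 fell by 0.51, a call lost in 3 of 19 alternatives (adjusted p up to 0.443), among them without wild-type replicate 2 (-0.42) and without transgenic replicate 2 (-0.46). Of 6 red cell markers 0 rose and 0 fell (adjusted p = 0.614), with Alas2 at -0.65 (adjusted p = 0.148), or -1.09 and past the threshold without transgenic replicate 2 (adjusted p = 0.00643). Of 19 peroxisome genes 4 rose and 4 fell (adjusted p = 0.62), with Acox2 at least 4.03-fold higher. For 8 tendon markers (2 rose, 1 fell, adjusted p = 0.62), 26 cytosolic ribosome genes (3 rose, 3 fell, or 2 and 0 adjusted over the list alone, adjusted p = 0.971) and 19 heme and iron genes (7 rose, 4 fell, or 8 and 4 adjusted over the list alone, adjusted p = 0.614), the median, mean and test differed in sign. The cytosolic ribosome list passed, as lower, in 1 of 19 alternatives, with arrays scaled to detected probes (adjusted p = 0.0222; range up to 0.983). Tnc rose by 1.86, Rpl3 by 0.998 and the iron exporter gene Slc40a1 fell by 1.34.

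Of the 38 lists, 12 were higher and 5 lower with the preset correlation of camera, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.256. For the fast-fibre, mitochondrial import and heat shock lists the estimates were -0.0019, 0.00027 and -0.030, below the preset 0.01. A larger correlation between genes therefore does not account for the loss of those calls. When the 6 arrays were split otherwise into 3 and 3, up to 17 lists passed as well, against 0 genes. Those splits mix the genotypes in both groups, so the 0 genes are no measure of chance. For lists not described otherwise, the counts adjusted over the list alone were the same as those over all genes tested.

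**Figure D3:**
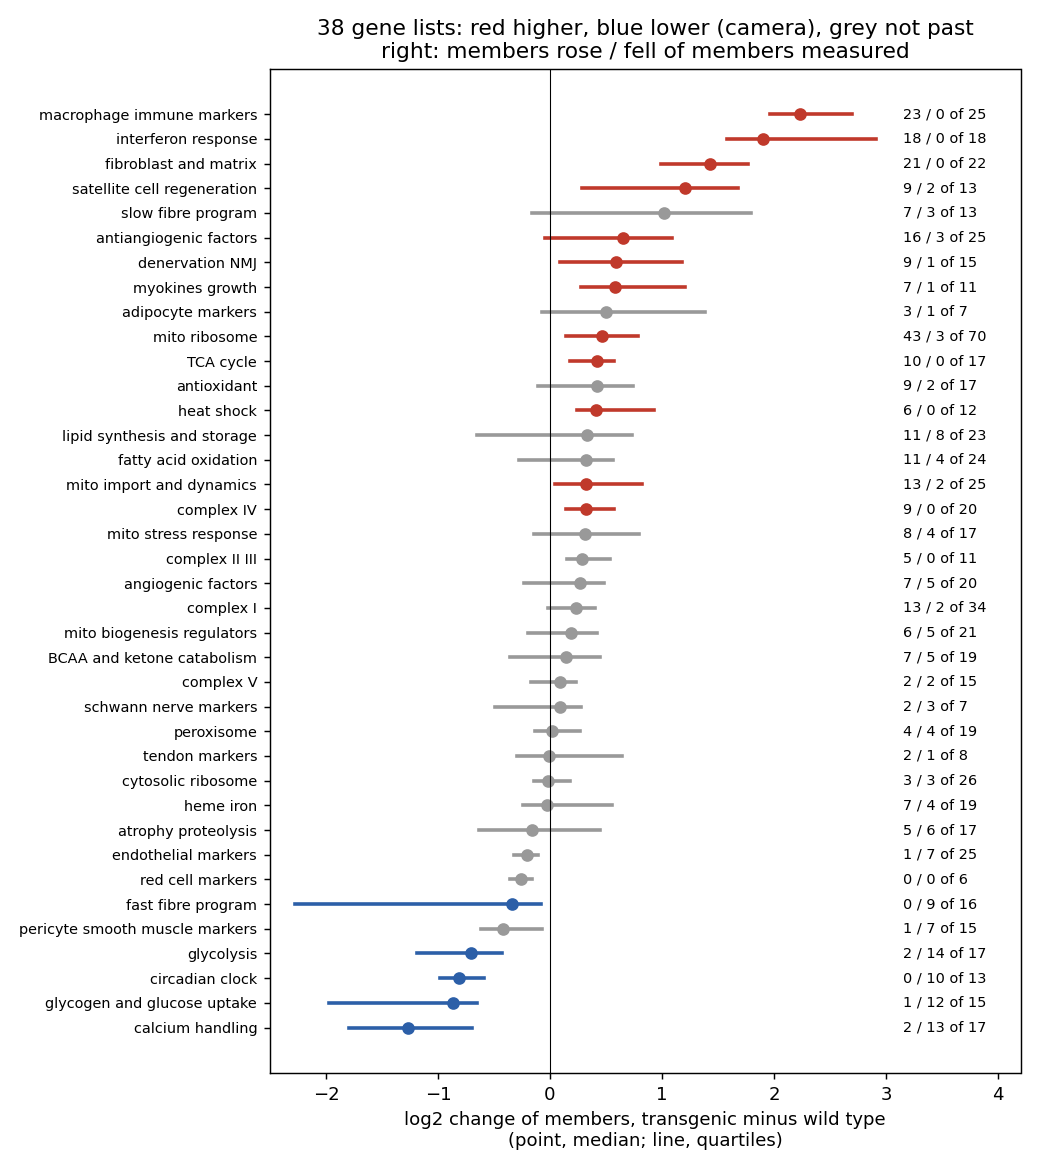
Median log2 change (points) and quartiles (lines) of the members of each of the 38 gene lists, transgenic minus wild type, with the numbers of members that rose and fell on the right. Macrophage and immune markers lie highest, with a median of 2.24, calcium-handling genes lie lowest, with a median of -1.27, and lists in grey did not pass the camera test.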

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

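Apart from the counts over other splits of the arrays, the tests in this part were chosen after the results were seen.

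Probes without exactly 1 gene symbol were left out of the comparison of genes. Of 2363 such probes above background, 1158 differed between the genotypes in limma at an adjusted p under 0.05, 503 higher and 655 lower in the arrays labelled transgenic, with log2 changes from -4.81 to 4.08. This signal lies in data that the comparison of genes did not use. Among all 17166 probes kept, 9168 passed the same threshold, so the probes without 1 symbol did not stand out by their share of calls.

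The Ppargc1b probe was lower, with a log2 change of -1.32, in the arrays labelled transgenic for PGC-1β. The scaling between arrays is argued against, since over 6 background, scaling and source settings the change nearest to 0 was -1.12 and the highest adjusted p 0.00475. An exchange of the 2 genotype labels, which would leave mitochondrial genes lower in the arrays labelled transgenic if PGC-1β raises them, stays open: the pooled shift of 191 genes in 7 mitochondrial lists was upward with camera p from 0.0456 to 0.73 over 4 scalings, with an estimated correlation. This test replaced an earlier one after its result was seen: the share of called genes that were higher, 93 of 104, or 57 of 90 with arrays scaled to detected probes, had argued against an exchange, but treated genes as independent. A probe that reads only the endogenous transcript also cannot be told apart from a real fall, since the array carries 1 annotated Ppargc1b probe and its sequence was not used here.

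Immune, interferon and matrix lists were higher in the arrays labelled transgenic. A smaller share of fibre RNA alone would raise the markers of all other cell types alike, and this is argued against: the macrophage median exceeded the endothelial median by 2.44 on the log2 scale, with 25 genes in each list (permutation p = 2e-05 over genes, which are not independent replicates). More immune cells and higher expression per cell cannot be told apart here: that 92% of the measured macrophage and immune markers rose, among them Lyz2 from 9.41 to 12.26 and Cd74 from 10.33 to 12.74, restates the pattern and would follow from either. Of the 25 markers 23 were above background on at least 1 wild-type array. A genotype effect on the fibres themselves was not tested.

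The 5613 genes past the threshold compare with 0 in limma in each of the other 9 splits of the 6 arrays into 3 and 3 (46 to 122 at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For gene lists, 17 passed with the real groups, the highest of the other splits was also 17, and 2 of 10 splits gave as many. With 10 splits no share under 0.05 can be reached. Each of the other splits puts both genotypes in each group, so the genotype difference widens the spread within groups and holds down the calls. The 0 genes are therefore no measure of chance.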

How the results depend on the processing

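Scaling to the probes detected on all arrays and counting genes measured in both groups were chosen after seeing the data. Ppargc1b stayed lower and past the threshold in all 19 alternatives, from -1.49 to -1.12 (adjusted p up to 0.00475). The 5613 genes became 4503 to 5092 without any 1 array, and 5097 when counted only where measured in both groups. Leaving out an array labelled transgenic also removed genes above background only on those arrays. Of the genes then tested 2056 to 2169 were higher, against 2801. With the replicate number as a block there were 5337 genes, 2673 higher and 2664 lower; same-numbered arrays did not deviate together (correlations -0.05, 0.03 and -0.00), and 2 of 6 arrays correlated best with their own number. Scaled to the median, 1607 genes were lower and 11 lists passed, 6 of them higher; the cause was not tested, but the median of all genes moved to 0.19. Testing every probe gave 9168 calls (4376 higher, 4792 lower), since more items were tested, and requiring 2-fold left 1726 (1082 and 644). With an estimated correlation 0 lists passed (0 higher, 0 lower), and fry, which does not compare a list with other genes, called 29 (22 higher). Of 17 lists called, 11 passed in all 19 settings of the same test. Uncalled lists changed sign as mean change relative to other genes. The cause was not tested, but the genes tested differed between some of these settings. Scaled to either median, complex I was -0.16, complex V -0.24, fatty acid oxidation -0.031 and heme and iron -0.092. With cyclic loess complex V was -0.032. In the authors' table complex V was -0.080, fatty acid oxidation -0.021, biogenesis regulators -0.0863 and heme and iron -0.0867. With probes detected on all arrays Schwann markers were -0.13 and cytosolic ribosome 0.051. Without 1 array Schwann markers ranged from -0.21 to 0.22, red cell markers from -0.59 to 0.22, cytosolic ribosome from -0.066 to 0.056 and peroxisome from -0.019 to 0.073. The Schwann list was below 0 without each array labelled transgenic and with probes detected on all arrays. In all of these settings Mal was no longer tested, so the range of that list does not measure the weight of single arrays. Kdm5d turned to 0.023 and Nrf1 to 0.15 scaled to the median, and Myh1 to -0.0072 scaled to detected probes, none called. Of 209 genes named or followed and called, 184 stayed called in every alternative that tested them. The other 25 lost the call in at least 1. Not all were tested in each alternative. Genes at background on every wild-type array, such as Cplx1, dropped out when 1 array labelled transgenic was left out. They also dropped out with only probes detected on all arrays. The BeadChip as a block was not run. Signal over background limits 479 genes that rose and 37 that fell to lower bounds.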

Other observations

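Genes in this part were picked one by one after their values were seen, as were both tests on neuronal genes, and no enrichment of a gene group was tested on them beyond the Rest targets. They are single genes and say nothing on the rest of their families. In addition to the fixed lists, 11 chemokine genes were looked at. Ccl4, Ccl5, Ccl12, Ccl3 and Ccl2, none of them above background on any wild-type array, were at least 10.3, 9.36, 8.71, 1.71 and 1.58-fold higher, lower bounds that do not rank the rises. Ccl7 and Ccl6, each above background on 1 wild-type array, rose by 3.68 and 1.59 on the log2 scale, Cxcl16 by 2.82, Ccl9 by 2.27, Cxcl1 by 1.04 (above background on 2 wild-type arrays) and Cxcl14 by 0.90. Among other single genes, H2-D1 rose by 1.83, H2-K1 by 1.64 and B2m by 1.73. The macrophage genes Ms4a7, Mpeg1 and Trem2 rose by 3.90, 3.80 and 3.47, the last 2 above background on 2 and 1 wild-type arrays. S100a8, a neutrophil gene, rose by 3.54 with a spread of 1.93 (SD, n = 3) among the arrays labelled transgenic, and was not past the threshold with a variance trend and robust fit (adjusted p = 0.0644). The stress genes Ankrd1 and Atf3 rose by 3.49 and 3.40.

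Some single genes of muscle metabolism had large changes. Smox, the spermine oxidase gene named above, fell by 4.53, and Amd2, encoding another enzyme of polyamine metabolism, fell by 2.93. Of the other polyamine genes looked at, Oaz2 fell by 0.64, Odc1 had a change of -0.39 and Azin1 of 0.59, calls lost in 3 and 2 of 19 alternatives (adjusted p up to 0.0695 and 0.0609), and Srm one of 0.22 (adjusted p = 0.345). The call of Odc1 was lost without wild-type replicate 1 (-0.36), without wild-type replicate 3 (-0.35) and without transgenic replicate 1 (-0.31), and that of Azin1 without the last 2 (0.46 and 0.45). Ampd1, the muscle AMP deaminase, fell by 2.66, and the change of Nos1, the neuronal nitric oxide synthase of muscle, was -2.86. Ckb, the brain-type creatine kinase, rose by 1.78. The muscle type Ckm had a change of -0.29 (adjusted p = 0.049) that was not past the threshold in 7 of 19 alternatives (adjusted p up to 0.133). Myom3, an M-band gene, rose by 2.64. The sex label was met on all 6 arrays, since the Y-linked Eif2s3y was above background on each by 1 of its 2 probes and none of the 4 Xist probes was above background on any.

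A set of 9 genes usually expressed in neurons, picked by their rises, was higher in the arrays labelled transgenic: Cplx1, Pacsin1, Hcn2, Elavl3, Sncb, Syn2 and Mapk8ip2 had no probe above background on any wild-type array and were at least 17.9, 17.0, 15.1, 12.9, 12.6, 7.49 and 6.59-fold higher, and Rnf208 and Nacad rose by 5.46 and 4.69. Other neuronal genes differed: Snap25, Tubb3, Stmn3, Syt4, Scg2, Chga and Bsn were not above background on any array, Uchl1 and Syp rose by 2.70 and 0.91, and Stmn2 fell by 0.90, a call lost with arrays scaled to the median (-0.53, adjusted p = 0.0637). Nerve tissue in the sample cannot be told apart from other causes. The 7 Schwann cell and nerve markers had a median change of 0.086 (bootstrap 95% interval -0.51 to 0.41), and 2 of them rose while 3 fell. However, 6 of them were above background on all wild-type arrays. Whether that signal came from nerve, or from other cells that would hide a small share of nerve, was not tested. The other 1, Mal, was at background on those arrays and at least 4.04-fold higher. The probes of Mbp, also a nerve marker, went both ways (-0.64, 0.996 and -0.48). Loss of repression by Rest was not settled either. Of 33 Rest target genes at background on every wild-type array, 5 (15.2%) were detected on at least 2 arrays labelled transgenic. Of 9002 other genes at background there, 807 were (8.96%, Fisher's exact p = 0.215). Mapk8ip2, picked above by its rise, is among the 5, so the share of targets is not independent of that choice. Rest itself was not above background on any array.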
